A study of Mus musculus with 6 samples.

How the data were processed

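The samples were 6 mNET-seq libraries from C57BL/6 mouse embryonic stem cells: 2 from control cells, 2 from a first Mettl3 knockout (KO1) and 2 from a second (KO2). Per the labels' protocols, chromatin was digested with micrococcal nuclease, RNA polymerase II was immunoprecipitated, and short RNA fragments from the precipitate were size-selected on a gel and made into small RNA libraries. Per the submitters' processing notes, the tools included CASAVA, Trimmomatic 0.38, HISAT2 2.1.0 and featureCounts, with the mm10 genome build. The role and settings of each, and whether strand was used in counting, are not given in the sources used here.

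The authors deposited 1 table of log2 values, named as an escaping index, for 68473 Ensembl transcripts in the 6 libraries, with no missing values. The index windows are not given in the sources used here. In every library, the values were log2 of a ratio plus a small offset: once 0.5 times the smallest value on the linear scale was taken off, the commonest ratio was exactly 1 (within 1e-09), as for a quotient of small whole numbers. The mean index rose with transcript length (Pearson's r = 0.804 with the log10 length and Spearman's rho = 0.812, across transcripts, which are not independent replicates), so the ratio is not scaled to length and a higher value goes with more signal downstream relative to the transcript's start. The index is a ratio within a transcript, and it measures neither the abundance of an RNA nor the total polymerase on a gene. The read depth per library is unknown, so no interval or detection limit based on counts is given.

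Transcript identifiers were matched without their version to GENCODE release M21, which is on the same build, and 68397 matched and 76 did not. Transcripts of a gene with identical values were taken once, and the others were averaged on the log2 scale, which gave 17349 genes, 13424 of them protein-coding. This average includes transcripts that start inside a gene, such as the 15199 retained-intron models, whose start is often not a promoter. The planned design assumed a linear index and a pseudocount. Since the deposited values were already log2 with an offset, they were tested as deposited, without a further pseudocount, and the planned pseudocount became an alternative. The planned filters removed no gene, since every value was finite. The libraries were not rescaled against each other, because a shift of the whole index is part of the comparison. Median centring and quantile normalization were alternatives.

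The 3 groups were fitted together with limma 3.58.1 in R 4.3.3 (group means, moderated variances with a trend on the mean index, two-sided). Contrasts were KO1 against control, KO2 against control, the average of both knockouts against control, and KO1 against KO2. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The fit has 3 residual degrees of freedom, to which limma's prior added 2.23. The procedure was tested on simulated data with the spread of the 17349 genes and 200 genes changed by known amounts. Changes of 2 on the log2 scale were recovered for 54.0% of genes in KO1, 54.2% in KO2 and 64.2% in the average, and changes of 1 for 13.0%, 12.0% and 28.0%. Over 5 runs, 14 of 349 calls in KO1, 17 of 348 in KO2 and 20 of 481 in the average were false.

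Before the data were examined, 19 gene lists were fixed, with 529 entries, of which 437 were measured. They cover m6A factors, nuclear RNA decay, naive pluripotency, primed and early lineages, endoderm and trophoblast, fibroblast (feeder) markers, 2-cell-like genes, immediate early genes, heat shock genes, p53 targets, cytosolic ribosomal proteins, oxidative phosphorylation, glycolysis, replication-dependent histones, Pol II pausing and elongation factors, chromatin regulators, bivalent Polycomb targets, the cell cycle, and noncoding RNA genes with snoRNA hosts. Older symbols were matched through RefSeq synonyms. Lists were tested with camera, which compares a list with all other genes, at a preset inter-gene correlation of 0.01, with adjustment over the 19 lists. An estimated correlation was the alternative, as was fry, which asks whether a list moves on balance in one direction and does not compare it with other genes.

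The genes named were set by a rule fixed in advance. For each contrast against control it takes up to 10 called genes per direction with the smallest p whose knockout libraries all lay on one side of both controls. Where fewer than 10 passed, up to 5 more are given as values only. Mettl3 and the other m6A factors are always included, as are the 2 to 4 members of each list with the smallest p in the average contrast, and for KO1 against KO2 the 5 smallest p per direction among called genes. Genes named outside this rule are marked as such. Of 118 genes taken by the rule, 56 overlap another annotated gene, and their values may include its reads. Tests in the closing section used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1. Alternatives were other pseudocounts, other scalings, a replicate block, a fit without the trend, fits of the compared groups alone, transcripts without averaging, and each library left out in turn. The replicate block, the fits of compared groups alone and the fits with a library left out have fewer residual degrees of freedom. Calls can therefore end in them without a smaller change. Alternatives chosen after seeing the data were the planned pseudocount, the offset taken off, 1 full-length transcript per gene and protein-coding genes alone. The list test of KO1 against KO2 was not in the planned design and was also added after seeing the data.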

Results

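Mettl3 is the catalytic subunit of the complex that writes the m6A mark on RNA. The study examined transcription in mouse embryonic stem cells with and without it. Cells were kept in serum medium with LIF and inhibitors of GSK3 (CHIR99021) and MEK (PD0325901), which hold them in a naive pluripotent state. mNET-seq sequences the short RNA held by RNA polymerase II after nuclease digestion of chromatin, and so maps where polymerases sit along genes. Each of the 3 groups (control, KO1 and KO2) had 2 libraries. The deposited escaping index, in log2, was available for 17349 genes. Replicate libraries correlated across transcripts at r = 0.978 in control, 0.978 in KO1 and 0.979 in KO2, and no 2 libraries held identical values. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

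The index was lower in both knockouts over most of the genome. The median over genes was 2.90 ± 0.0027 (SD, n = 2) in control, 2.69 ± 0.0089 (SD, n = 2) in KO1 and 2.58 ± 0.0026 (SD, n = 2) in KO2. On the linear scale this was 13.2% below control in KO1 and 19.7% below control in KO2. The fall was larger with 1 full-length transcript per gene. The median ratio was then 17.5 and 17.57 in the control libraries, 13.81 and 13.97 in KO1, and 12.18 and 12.36 in KO2. Of the 17349 genes, 70.3% had a lower index in KO1 and 78.7% in KO2. All 4 knockout libraries lay below both controls, by far more than the spread between replicates. With 2 against 4 libraries, the exact permutation test (15 splits, the one-sided share doubled) gave p = 0.133, the smallest p this procedure allows. By absolute difference, only the observed split of the 15 was as large, a share of 0.067. Mettl3 itself (chromosome 14, 52294841 to 52305128, mm10) had an index of 0.64 ± 0.076 in control, 0.69 ± 0.117 in KO1 and 0.36 ± 0.106 in KO2 (SD, n = 2 each), and it passed the limma test in neither knockout (adjusted p = 0.902 and 0.304). A ratio within a gene does not check the loss of its product.

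**Figure D1:**
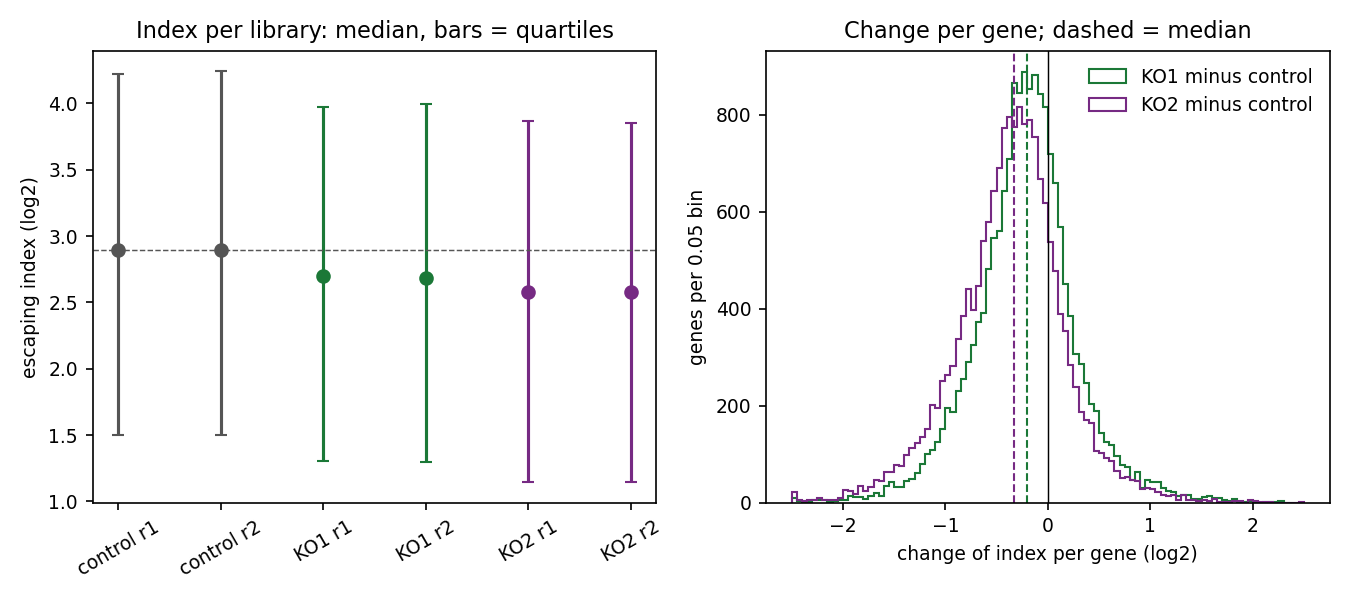
Left, escaping index (log2) per library over 17349 genes, with points for the median and bars for the quartiles; right, histogram of the change per gene (log2) in KO1 and KO2 against the mean of the 2 controls, with changes beyond 2.5 drawn at the edge. The knockout medians lie below the dashed control level, and the median changes per gene are -0.21 in KO1 and -0.34 in KO2.

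In KO2 against control, the index fell in Tctn3, a protein of the ciliary transition zone, by 2.23 ± 0.16 (SE, log2), from 4.98 ± 0.050 to 2.75 ± 0.163 (SD, n = 2). It also fell in Slc25a35, a mitochondrial carrier (-2.21 ± 0.15), in Cemip2, a cell-surface hyaluronidase (-1.99 ± 0.15), and in Bard1, the partner of Brca1 (-1.97 ± 0.16). Further genes that fell were Elovl7, a fatty acid elongase (-1.93 ± 0.15), Eif5a2, a translation factor (-1.83 ± 0.13), Btbd3 (-1.81 ± 0.13), the homeobox gene Prrx2 (-1.80 ± 0.13), the Hsp70 co-chaperone Bag3 (-1.58 ± 0.13) and Apbb3, an adaptor of the amyloid precursor protein (-1.49 ± 0.12). Each had a limma adjusted p of 0.0365, with both KO2 libraries below both controls. Tctn3 lies on chromosome 19 (40596446 to 40612233), Bard1 on chromosome 1 (71027498 to 71103146) and Prrx2 on chromosome 2 (30845444 to 30878657).

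Few genes moved the other way in KO2. The index rose in Gm27002, a sense-intronic noncoding RNA (2.01 ± 0.15), from 0.13 ± 0.088 to 2.15 ± 0.066 (SD, n = 2). It rose in Gm8778 (2.16 ± 0.34), in Oas1d, of the oligoadenylate synthetase family (1.87 ± 0.24), in Gm10509 (1.86 ± 0.28), in Jrkl (1.63 ± 0.20), in the serine protease inhibitor Serpinb6b (1.53 ± 0.19) and in B230110C06Rik (1.32 ± 0.17). It also rose in Gm26582 (1.27 ± 0.20), Gm49776 (0.85 ± 0.13) and Gm47842, a processed pseudogene (0.85 ± 0.13), with limma adjusted p from 0.0365 to 0.0387 over these 10 genes. Gm10509 was at 0.002 in KO2 replicate 1, a ratio of 1 plus the offset, so its rise may rest on few reads. Gm8778 was at 0.172 in both KO1 replicate 1 and KO2 replicate 2, so its rise may as well. Read depth is unknown, so other genes named here may also rest on few reads. Of 1225 genes called in KO2, 1197 were lower and 28 higher. With 1 full-length transcript per gene, the number of genes changed in KO2 against control was 3112 (73 higher, 3039 lower). The number was also larger with protein-coding genes alone. No gene was called once each library was centred on its median, where the genes at an unadjusted p under 0.05 split into 1448 higher and 2141 lower, against 320 and 5255 without centring. Centring moves every change up by the same amount, so falls shrank and rises grew. Tctn3 was then at -1.92, Bard1 at -1.65, Gm27002 at 2.33 and Oas1d at 2.19. No gene was called when any 1 of the 6 libraries was left out, or when KO2 and control were fitted alone.

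In KO1 against control, no gene passed the limma test (smallest adjusted p = 0.0557), while 4013 genes had an unadjusted p under 0.05, of which 581 were higher and 3432 lower. The 5 genes with the smallest p and a lower index, none of them passing, were Gm5511, a processed pseudogene (-3.19 ± 0.15), Spo11, which makes the DNA breaks of meiosis (-2.67 ± 0.20), Prrx2 (-2.26 ± 0.13), Cemip2 (-1.77 ± 0.15) and Cpe, a peptide-processing carboxypeptidase (-1.72 ± 0.14). Those with a higher index, also not passing, were Gm27002 (1.79 ± 0.15), 2210406O10Rik (1.39 ± 0.14), Trh, the thyrotropin-releasing hormone gene (1.14 ± 0.13), Gm47842 (1.12 ± 0.13) and Tuba1a, an alpha-tubulin (1.09 ± 0.13). After median centring 1336 genes were higher and 1697 lower at an unadjusted p under 0.05. The number of genes changed in KO1 against control was 109 with protein-coding genes alone (5 higher, 104 lower).

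Averaged over both knockouts, genes in which the index fell included Spo11 (-2.43 ± 0.18), Gm5511 (-2.29 ± 0.13), Prrx2 (-2.03 ± 0.12) and Cemip2 (-1.88 ± 0.13). Prrx2 had an index of 5.16 ± 0.038 in control, 2.90 ± 0.023 in KO1 and 3.35 ± 0.142 in KO2 (SD, n = 2 each). Tctn3 (-1.76 ± 0.14), Bard1 (-1.73 ± 0.14), Elovl7 (-1.60 ± 0.13), Eif5a2 (-1.60 ± 0.11), Btbd3 (-1.51 ± 0.11) and Abcc8, a subunit of the ATP-sensitive potassium channel (-1.41 ± 0.11), also fell. The index rose in 4933430L12Rik (2.12 ± 0.32), Gm8778 (1.94 ± 0.29), Gm27002 (1.90 ± 0.13), Jrkl (1.30 ± 0.17), Tsga10ip (1.19 ± 0.16), B230110C06Rik (1.19 ± 0.14), 2210406O10Rik (1.14 ± 0.12), Serpinb6b (1.08 ± 0.16), Gm47842 (0.98 ± 0.11) and Tuba1a (0.85 ± 0.11), with limma adjusted p from 0.0386 to 0.0410 over the 20 genes. 4933430L12Rik was at 0.004 in control replicate 2, a ratio of 1 plus the offset, so its rise may rest on few reads. The rise of Gm8778 may as well, as given for KO2. In all, 1038 genes were called, 1004 lower and 34 higher, and 803 of them were also called in KO2. With 1 full-length transcript per gene 2679 genes were called in the average, and with protein-coding genes alone 1784. At an unadjusted p under 0.05, 387 genes were higher and 4919 lower, against 1454 and 2090 after median centring. Centred changes stayed large, with falls smaller and rises larger: Prrx2 was at -1.77, Spo11 at -2.17, Gm27002 at 2.16 and Tuba1a at 1.11. Median centring, or leaving out any 1 library, ended every call, and with the 4 knockout libraries as 1 group the number of genes changed in the average of both knockouts against control was 294 (7 higher, 287 lower).

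The p53 targets, genes induced by the p53 tumour suppressor, had a lower index as a group. In the average of both knockouts all 18 measured members were below control, with a median of -0.48 against -0.27 over all genes. Of these, 4 fell and 14 did not pass: Eda2r, a receptor of the TNF receptor family (-0.81 ± 0.11), Mdm2, the ubiquitin ligase that degrades p53 (-0.67 ± 0.11), Trp53inp1, a stress-induced cofactor of p53 (-0.73 ± 0.12), and Sesn2, a leucine sensor (-0.95 ± 0.18), with limma adjusted p from 0.0388 to 0.0498. Adjusted over the list alone, 8 fell. The list's median was -0.49 in KO1 and -0.67 in KO2. Camera gave an adjusted p of 0.0196 for the average, 0.0615 for KO1 and 0.0362 for KO2, and with an estimated correlation the adjusted p was 0.724, 0.572 and 0.461. For the list p53 targets, avg (average) calls were lost with 1 full-length transcript per gene (adjusted p = 0.0781, although the median was lower, at -0.70 in the average and -0.94 in KO2), with protein-coding genes alone (0.0541) and without control replicate 1 (0.0778). For the list p53 targets, KO2 calls were lost in these (0.0900, 0.0840 and 0.0920) and without any other 1 library (0.0669 to 0.121) except KO2 replicate 2 (0.0443).

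The replication-dependent histones, which package newly made DNA, differed between the knockouts. In KO1 18 of 21 measured members had a higher index than control, with a median of 0.15, and in KO2 19 of 21 had a lower one, with a median of -0.57. In KO2 the index fell in 4 members over all genes and in 13 adjusted over the list alone, among them Hist1h4c (-1.32 ± 0.19), Hist1h3d (-1.17 ± 0.13) and Hist1h2bc (-1.01 ± 0.14), each with a limma adjusted p of 0.0365 over all genes. In KO1 no member passed, and these genes were at 0.65 ± 0.19, 0.39 ± 0.13 and 0.34 ± 0.14. Camera gave an adjusted p of 1.49e-05 in KO1 and 0.0429 in KO2, and 0.235 and 0.461 with an estimated correlation. That estimate was -0.01, so the calls lost there do not show an effect of correlated genes. For the list replication-dependent histones, KO2 calls were lost when any 1 library was left out (adjusted p from 0.0799 to 0.151), with 1 full-length transcript per gene (0.271), with protein-coding genes alone (0.0840) and with the planned (0.0758) or a 10 times larger pseudocount (0.214), while the KO1 call held in all of these. For the list replication-dependent histones, KO1 medians shrank to 0.07 with the planned (0.4) and 0.01 with the larger pseudocount (4). A pseudocount pulls the changes of low ratios toward no change whatever their cause, so this does not test the rise. A rise above control itself stays uncertain, since no member passed, although no other gene passed in KO1 either. Both KO1 libraries lay above both controls in 10 of 21 members, against 16.7% by chance. Fry, which tests the list against no change, gave an adjusted p of 0.00229 in KO1. Copies of histone genes are near-identical, so single members are uncertain where reads could be shared.

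The noncoding RNA genes and snoRNA hosts had a higher index relative to other genes in KO2, with a median of -0.105 over 16 members against -0.34 over all genes (camera adjusted p = 0.0429, and 0.461 with an estimated correlation). The estimate was 0.016, near the preset 0.01, and that option has few degrees of freedom, so the loss is weak evidence of correlated genes. The 3925 genes that are not protein-coding also had a higher median in KO2 (-0.205) than the 13424 protein-coding genes (-0.359), so the difference need not be particular to this list. No member passed; Epb41l4aos was at -0.80 ± 0.22, below the median of all genes, Snhg8 at -0.55 ± 0.22, Snhg6 at 0.33 ± 0.14 and Kcnq1ot1, an imprinted antisense RNA, at -0.41 ± 0.22. For the list noncoding RNA genes and snoRNA hosts, KO2 calls ended without any 1 of the 6 libraries (adjusted p from 0.0784 to 0.121) and with 1 full-length transcript per gene (0.255, with a median of -0.39). The median was 0.01 with the planned and 0.04 with a 10 times larger pseudocount, and fry, which tests against no change, placed the list below control (adjusted p = 0.0444).

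Without rescaling, the remaining lists were not called against other genes in any of the 3 contrasts with control. After median centring, camera called Pol II pausing and elongation factors higher in KO2 (adjusted p = 0.0385) and glycolysis higher in the average (0.0472). Without centring their adjusted p was 0.544 and 0.799 with an estimated correlation, which was not run on centred values. The values that follow are for the average of both knockouts. Among 20 m6A factors the median was -0.16, and the index fell in the m6A reader Ythdf3 (-0.96 ± 0.11) while 19 did not pass, such as the demethylase Alkbh5 (-0.62 ± 0.13), the writer subunit Cbll1 (-0.63 ± 0.16), Igf2bp3 (-0.32 ± 0.13), Wtap (-0.29 ± 0.13) and Mettl14 (-0.17 ± 0.22). Of those not passing, 3 were above control, namely the demethylase Fto (0.36 ± 0.16), the writer subunit Zc3h13 (0.27 ± 0.13) and Igf2bp2 (0.07 ± 0.11). The others were Mettl3 (-0.12 ± 0.15), Ythdf2 (-0.24 ± 0.13), Rbm15 (-0.26 ± 0.17), Virma (-0.28 ± 0.24), Ythdc2 (-0.16 ± 0.24), Hnrnpa2b1 (-0.16 ± 0.13), Ythdc1 (-0.15 ± 0.11), Igf2bp1 (-0.10 ± 0.11), Ythdf1 (-0.04 ± 0.11), Rbm15b (-0.03 ± 0.19) and Hnrnpc (-0.00 ± 0.10). Adjusted over the list alone, 2 fell. Among 25 naive pluripotency genes, with a median of -0.07, Fgf4 fell (-0.78 ± 0.12), and Tfcp2l1 (-0.51 ± 0.11), Klf4 (-0.51 ± 0.13) and Dppa2 (-0.38 ± 0.12) did not pass. Of 29 cell cycle genes, with a median of -0.24, 3 fell, namely the mitotic kinase Aurkb (-0.98 ± 0.12) and the cyclins Ccnb2 (-0.89 ± 0.12) and Ccna2 (-0.76 ± 0.14). Of 38 chromatin regulators, with a median of -0.14, the H3K9 methyltransferase Setdb1 fell (-1.13 ± 0.13), Ehmt1 (-0.50 ± 0.10), Suv39h1 (-0.64 ± 0.14) and Ash2l (-0.52 ± 0.11) did not pass, and 4 fell adjusted over the list alone. Of 28 Pol II pausing and elongation factors, with a median of -0.16, none passed, with Supt4a at -0.60 ± 0.14 and Ell2 at -0.43 ± 0.10. With 1 full-length transcript per gene, Ell2 (-0.92, limma adjusted p = 0.0294) and Cdc73 (-0.57, 0.0491) passed, while Supt4a (0.073) and Tcea1 (0.288) did not. None of 18 nuclear RNA decay genes passed with averaged values, although all 18 were below control, with a median of -0.35, and 3 fell adjusted over the list alone (Tent4b, a poly(A) polymerase, was at -0.75 ± 0.15 and Pabpn1 at -0.58 ± 0.12). With 1 full-length transcript per gene, Tent4b passed (-0.89, limma adjusted p = 0.0463), while Pabpn1 (0.137), Exosc3 (0.124) and Exosc4 (0.241) did not.

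Of 77 cytosolic ribosomal protein genes, with a median of -0.20, 3 fell (Rps3a1, -0.83 ± 0.10; Rpl34, -0.72 ± 0.13; Rpl41, -0.84 ± 0.15), and 1 did so adjusted over the list alone. Of 42 oxidative phosphorylation genes, with a median of -0.35, Ndufb9 fell (-0.66 ± 0.12), Ndufs3 (-0.59 ± 0.13) and Sdhd (-0.63 ± 0.14) did not pass, and none fell adjusted over the list alone. Of 18 glycolysis genes, with a median of -0.12, the lactate transporter Slc16a1 fell (-0.65 ± 0.12), and Pfkp (0.29 ± 0.11), Eno1 (0.20 ± 0.11) and Slc2a1 (-0.24 ± 0.11) did not pass. Of 16 heat shock genes, with a median of -0.20, Bag3 (-0.88 ± 0.11) and Hspa4l (-0.70 ± 0.12) fell. None of 22 immediate early genes passed, with a median of -0.45 and Ier3 at -0.62 ± 0.14 and Junb at -0.76 ± 0.18. With 1 full-length transcript per gene, Fosb passed (-1.11, limma adjusted p = 0.0374), while Ier5 (0.0588), Ier3 (0.0769) and Junb (0.0846) did not. Of 16 primed and early lineage genes, with a median of -0.33, the organizer gene Gsc fell (-1.12 ± 0.17), and Nes (-0.62 ± 0.16), Dnmt3b (-0.55 ± 0.20) and Hand1 (-1.18 ± 0.42) did not pass. Of 11 endoderm and trophoblast genes, with a median of -0.69, Ascl2 fell (-1.03 ± 0.12), Lama1 (-0.48 ± 0.11) and Pdgfra (-0.81 ± 0.22) did not pass, and 4 fell adjusted over the list alone. Of 10 fibroblast markers, with a median of -0.49, Twist1 (-2.41 ± 0.23) and Thy1 (-0.81 ± 0.14) fell. Of 10 measured bivalent Polycomb targets, with a median of -0.39, Hoxb13 fell (-1.36 ± 0.21), and Hoxa7 (-1.48 ± 0.41), Gata3 (0.64 ± 0.26) and Hoxb9 (-0.31 ± 0.13) did not pass. Twist1 was at 0.002 in KO1 replicate 1 and KO2 replicate 2, a ratio of 1 plus the offset. Gsc in KO2 replicate 2 and Hoxb13 in KO1 replicate 2 held the same value, so these falls may rest on few reads. The 2 measured 2-cell-like genes had a median of -0.40, and Eif1a fell (-0.55 ± 0.10) while Usp26 (-0.26 ± 0.31) did not pass. The limma adjusted p of the single genes that fell in these lists lay between 0.0386 and 0.0493. With 1 full-length transcript per gene, Ehmt1, Ndufs3, Klf4, Lama1 and Dnmt3b, given above as not passing, passed (limma adjusted p from 0.0292 to 0.0420). Slc16a1, Ndufb9 and Eif1a, given above as falling, did not pass then (0.0527 to 0.0577).

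**Figure D2:**
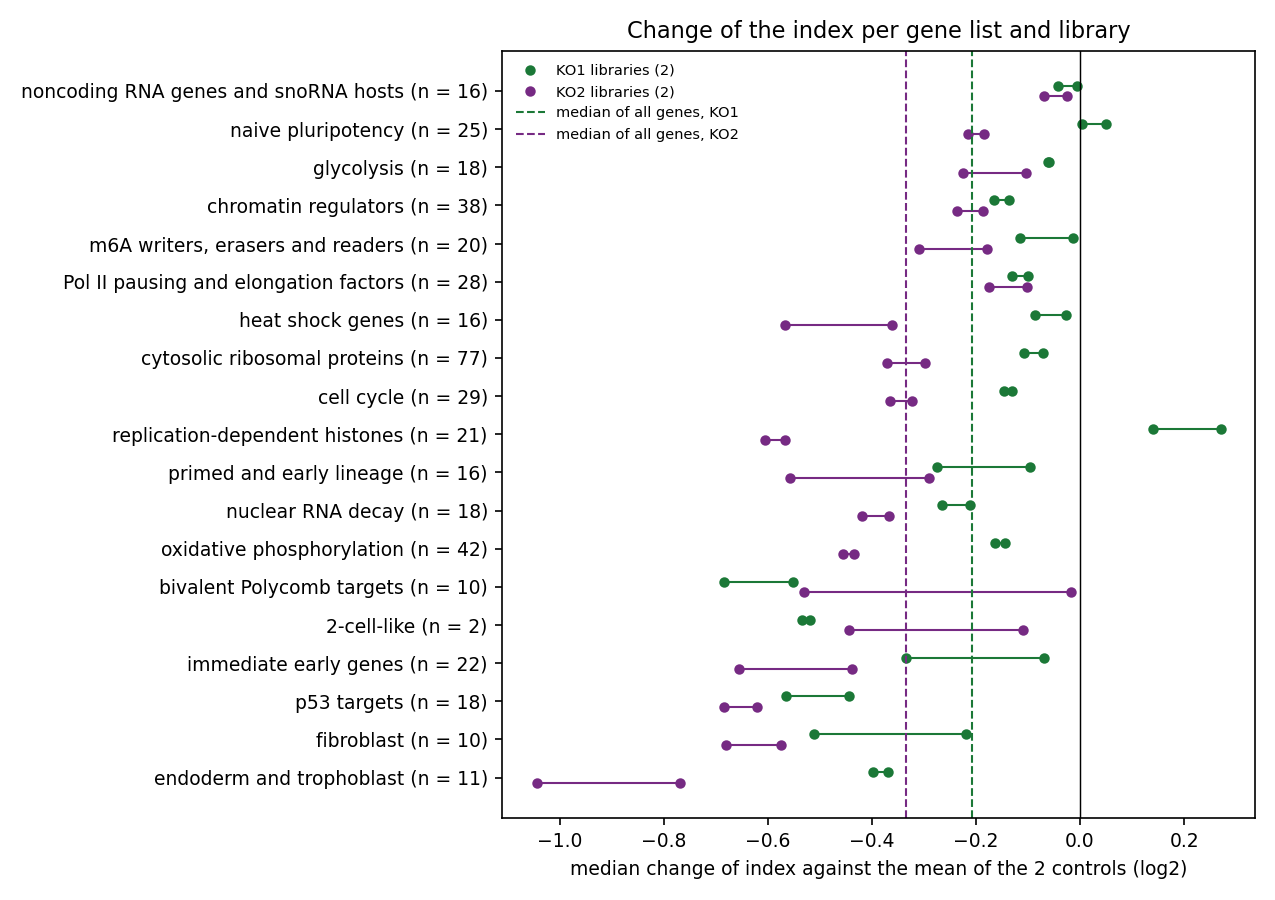
Median change of the index (log2) of each of the 19 lists in the 2 KO1 and the 2 KO2 libraries against the mean of the 2 controls, with lines joining the libraries of a knockout, dashed lines for the median of all genes and n the measured members. Histones lie at 0.14 and 0.27 in KO1 and at -0.57 and -0.61 in KO2, and p53 targets lie left of both dashed lines.

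KO1 and KO2 were compared directly to ask where the knockouts differ. The histone list had a median 0.78 higher in KO1 than in KO2, with 20 of 21 members higher in KO1 and 14 of them adjusted over the list alone, led by Hist1h3d (1.57 ± 0.13), Hist1h4c (1.97 ± 0.19) and Hist1h2bc (1.35 ± 0.14). Heat shock genes, the chaperones of misfolded proteins, were 0.48 higher in KO1 by the median, with 12 of 16 members higher and 8 of them adjusted over the list alone, among them Bag3 (1.40 ± 0.13) and Hspa1a (1.18 ± 0.26). Hspa1a was at 0.002 in KO2 replicate 1, a ratio of 1 plus the offset, so its difference may rest on few reads. Cytosolic ribosomal protein genes were 0.24 higher, against 0.12 for all genes, with 62 of 77 members higher. Adjusted over the list alone, 1 of them was higher and 2 were lower. Camera gave adjusted p of 2.28e-08, 0.0113 and 0.0204 for the 3 lists, and 0.131, 0.523 and 0.446 with an estimated correlation. No single gene passed the limma test (smallest adjusted p = 0.143), and 2786 had an unadjusted p under 0.05, of which 2235 were higher and 551 lower in KO1, against 1434 and 1011 after median centring. For the list replication-dependent histones, diff (difference) medians shrank from 0.78 to 0.34 with the planned and 0.11 with the 10 times larger pseudocount, with the call kept. Adding a pseudocount shrinks the differences of low ratios whatever their cause. For the list cytosolic ribosomal proteins, diff calls were lost after median centring (adjusted p = 0.103), after quantile normalization (0.192), with a 10 times larger pseudocount (0.0696), with 1 full-length transcript per gene (0.298) and without any 1 library (from 0.0509 to 0.156). For the list heat shock genes, diff calls were lost without KO1 replicate 2 (0.0591), without KO2 replicate 1 (0.156) and with 1 full-length transcript per gene (0.123).

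**Figure D3:**
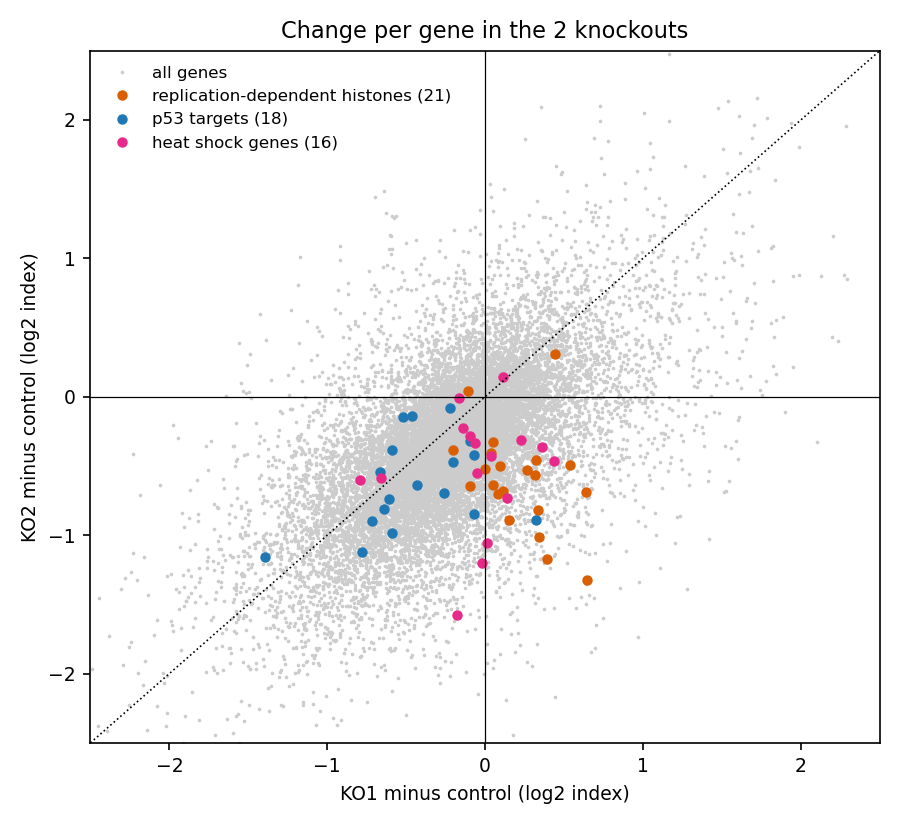
Change of the index (log2) per gene in KO1 (x axis) and KO2 (y axis) against the same 2 controls, with all genes in grey and histones, p53 targets and heat shock genes in colour; the dotted line marks equal change, and 31 genes lie outside the axes. Most histone genes lie to the right of 0 on the x axis and below 0 on the y axis.

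Across genes, the changes in KO1 and KO2 correlated at r = 0.593, and 76.2% of genes had the same sign. Both changes use the same controls, and 100 simulations of unchanged groups gave a mean r of 0.501 and 66.7% of the same sign (genes are not independent replicates). The simulated groups had no shift of the whole index, whereas 70.3% of genes were lower in KO1 and 78.7% in KO2. Such a shift by itself raises the share of the same sign, so the 2 shares do not measure agreement gene by gene. The covariance was 0.163 against 0.0679 in the simulations, a difference of 0.095. With a separate control library for each knockout, r was 0.255 and 0.262 and the covariance 0.0889 and 0.0908 for the 2 ways of assigning them. These changes share no library, so no correlation is built in for unchanged groups, and the simulated values above are not their comparison.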

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

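The test on linker histones was chosen after the histone difference was seen. The knockouts differed in 3 lists in the direct test of KO1 against KO2, which was itself added after seeing the data: replication-dependent histones (median 0.78 higher in KO1, log2), heat shock genes (0.48) and cytosolic ribosomal proteins (0.24). None of the 3 calls held with an estimated correlation (camera adjusted p = 0.131, 0.523 and 0.446). The estimates were -0.01, 0.263 and 0.006, against the preset 0.01. That option tests on 3 residual degrees of freedom, so for the histones and ribosomal proteins the lost calls do not show an effect of correlated genes. Among 10000 random lists matched on gene length and mean index, the first 2 medians lay at percentiles 99.99 and 99.79, and that of the ribosomal proteins lay inside the middle 95%, as a description of these libraries. For the list replication-dependent histones, diff (difference) medians were 0.34 with the planned pseudocount and 0.11 with a 10 times larger one, which by itself shrinks the differences of low ratios.

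The histone difference was weighed further. Both KO1 libraries lay above both KO2 libraries in 19 of 21 members, against 35.7% of all genes and 16.7% by chance. Both KO2 libraries lay below both controls in 19 members, and both KO1 libraries above both controls in 10, with the same 16.7% by chance. A general difference in how short single-exon genes were measured is argued against as the whole cause. The 322 other such protein-coding genes differed by a median of 0.15 relative to all genes (95% bootstrap interval over genes 0.045 to 0.227), against 0.66 for the histones. They too were higher in KO1 and were not matched to the histones in length or index, so a part from this cause stays open. Reads shared between near-identical core histone copies are argued against as the whole cause by 4 linker histone genes. These, Hist1h1a, Hist1h1b, Hist1h1c and Hist1h1e (all but Hist1h1a outside the rule for naming genes), differed by a median of 0.69, from 0.55 to 0.79. They belong to the same list, so their direction was largely known when the test was chosen. Shared reads among the core copies stay open. A different share of cells in S phase cannot be told apart from other causes: 11 other S phase genes differed by 0.13 relative to all genes, but the index is a ratio within a gene and need not follow cell cycle phase. A difference between the knockout lines themselves also stays open and is untested, since each line is represented by 2 libraries whose origin is not stated.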

How the results depend on the processing

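Alternatives chosen after seeing the data were the planned pseudocount, the offset taken off, 1 full-length transcript per gene and protein-coding genes alone, and the list test of KO1 against KO2 was also added then. Taking off the offset, a fit without the trend and a pseudocount 10 times smaller kept each count of called genes within 1.5 times of its value. The values that follow are genes changed in KO1 against control, genes changed in KO2 against control and genes changed in the average of both knockouts against control. With each library left out in turn, the lone sample being assumed to vary like the other groups, 0 genes were called in KO1, KO2, the average and KO1 against KO2. The median difference of the average knockout from control stayed between -0.263 and -0.257, the correlation of changes lay between 0.527 and 0.684, and camera called 0 to 1 lists in the average, 1 in KO1, 0 to 1 in KO2 and 1 to 2 between knockouts. Median centring and quantile normalization each gave 0 genes in KO2 and 0 in the average and set the median difference to 0.00 by construction, with 3 and 4 lists in the average, and 4 and 4 in KO2. After centring these were p53 targets, noncoding RNA genes and glycolysis in the average, and p53 targets, noncoding RNA genes, histones and Pol II factors in KO2. Without averaging by gene, 7146 transcripts were called in KO2 and 6157 in the average (median difference -0.275). With 1 full-length transcript per gene, 3112 genes were called in KO2 and 2679 in the average (median difference -0.426), with 0 lists in the average and 0 in KO2. With protein-coding genes alone, 109 genes were called in KO1, 2101 in KO2 and 1784 in the average (median difference -0.297), with 0 lists in the average and 0 in KO2. Fitting the compared groups alone gave 0 genes in KO2, and the 4 knockouts as 1 group gave 294 in the average. A pseudocount 10 times larger moved the median difference to -0.184 and the correlation to 0.650, and the planned pseudocount moved the former to -0.252. Separate controls gave correlations of 0.255 and 0.262, to which no shared control adds. An estimated correlation gave 0 lists in the average, 0 in KO1, 0 in KO2 and 0 between knockouts, and fry, which does not compare a list with other genes, gave 18, 10, 17 and 10. Fry put the noncoding RNA list (median -0.105 in KO2) below control, whereas camera put it above other genes. Where a value moved, the cause was not tested. The planned filters removed no gene and gave no new value. In the counts that follow, weaker means that a call at an adjusted p under 0.05 was lost, whatever the size of the change. The results counted include the 10 KO1 genes given as values only, which had no call to lose. With the compared groups alone, these are the 10 the same, and the 20 weaker are all the KO2 genes counted. Of 58 results on genes and lists, 43 to 45 were weaker with any 1 library left out, 41 after median centring, 41 after quantile normalization and 6 with 1 full-length transcript per gene, and with the compared groups alone 20 were weaker and 10 the same. Some m6A factors that did not pass changed sign: Mettl3 in KO2 was at -0.28 but at 0.03 after centring, and Mettl14 in the average at -0.17 but at 0.09.

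The replicate numbers share only a number: deviations of same-numbered libraries correlated at -0.016, -0.002 and 0.027. With a replicate block, 0 genes were called in KO2 and 0 in the average, and camera called 1 list in KO2 (p53 targets). Of the 58 results, which include the KO1 genes with no call to lose, 42 lost their call. The block left every change as it was and took up a residual degree of freedom, so only the p-values moved. For the list replication-dependent histones, KO2 calls ended with the block (camera adjusted p = 0.0838), as they did for the list noncoding RNA genes and snoRNA hosts, KO2 (0.0658). The read depth is unknown, so how far counting error limits each gene cannot be given; the spread between replicates had a median SD of 0.222 per gene (0.058 to 0.762 from the 5th to the 95th percentile).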

Other observations

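The tests of outer against internal starts and of the genes with the least spread were chosen after the lower index was seen. The fall of the index depended on where a transcript model starts. In 7395 genes with both kinds of model, transcripts starting within 200 bp of the outermost start had a median change of -0.36 in KO1 and -0.54 in KO2. Transcripts of the same genes starting over 1000 bp inside were at 0.02 and 0.01. The 2 libraries of each knockout gave nearly equal outer values (-0.371 and -0.361 in KO1, -0.543 and -0.530 in KO2). By annotation class, the largest changes were in bidirectional promoter lncRNAs (173 transcripts, -0.39 in KO1 and -0.57 in KO2), which start at promoters of coding genes on the other strand, and in protein-coding transcripts (33985, -0.28 and -0.43). Retained-intron models (15199) were at -0.12 and -0.18, and processed pseudogenes (789) at 0.05 and -0.10.

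For the lower index across genes in both knockouts, the offset added before the log is argued against, since the median difference of the average knockout remained -0.26 with the offset taken off. A single factor per library acting alike on every index is argued against as the whole cause. Within genes, the change at outer starts lay below that at internal ones (median difference -0.448, 95% bootstrap interval -0.461 to -0.430). The median differences were -0.370 and -0.367 in the KO1 libraries and -0.537 and -0.528 in the KO2 libraries. Bootstrap intervals in the closing sections measure spread between genes, which are not independent replicates, and not spread between libraries. Few reads per gene stay open, since the read depth is unknown and replicate spread is not a read count. The sixth of genes with the least replicate spread still changed by -0.22 (95% bootstrap interval -0.235 to -0.209). It had the smallest fall of the sixths, the others lying between -0.239 and -0.309, so the fall is not limited to genes with a wide replicate spread. Promoter and gene body signal are not given separately, so which of them differs was not tested. A difference between groups in nuclease digestion, precipitation or fragment selection that acts on promoter-proximal RNA was not tested and stays open, as does the biological difference between the groups.

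For the lower p53 targets, gene length and index level cannot be told apart from a specific effect. Among 10000 random lists matched on both, the list's median lay at percentile 3.07 in the average, inside the middle 95%, but at 1.27 in KO1 and 0.52 in KO2, outside it, and the rule that all 3 contrasts decide was set after these values were seen. Internal transcript starts also stay open: with 1 full-length transcript per gene the list lay -0.299 from all genes, further than the -0.214 of the averaged values, but the 95% bootstrap interval of -0.516 to -0.018 reaches past the bound of -0.1 set beforehand (the bootstrap intervals were added after the values were seen).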
